A study of Drosophila melanogaster with 8 samples.

How the data were processed

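RNA was sequenced from whole guts of adult female Drosophila melanogaster. The 8 libraries used here form 2 groups of 4, which the labels describe as biological repeats: control guts, in which GFP was expressed from a UAS transgene, and guts in which the B-type lamin LamDm0 was expressed from a UAS transgene in enterocytes, the absorptive cells of the midgut. Per the labels, flies were kept at 18 °C, females aged 2 to 4 days were moved to 29 °C for 2 days, and RNA was taken from dissociated guts. Poly(A) RNA was selected from 100 ng of total RNA and made into libraries with a kit that marks strand. 12 such libraries were pooled and read as single reads of 50 nt on 2 lanes. Of these 12, the 4 that belong to neither group were not used here. The labels give no lane, day or batch for a library.

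The values are counts of reads per gene for 17559 genes, deposited by the authors as 1 table with a column per library. They are whole numbers and sum to a different total in each library, so they were taken as raw counts. Per the submitters' processing notes, the genome build was BDGP6 and the tools were TopHat2 2.0.13, HTSeq 0.6.0 and DESeq2 1.10.1, with no role given for any of them. The strand setting, the treatment of reads that match several genes and the annotation release are not given in the sources used here. In the annotation used here, 68 protein-coding genes have all their exons covered by exons of the opposite strand, and 14 of them had at least 1000 counts over the 8 libraries. Genes with near-identical copies are therefore reported as uncertain, and so are antisense RNAs. The authors also deposited a table of their own comparison of the groups, with a log2 fold change, a p-value and an adjusted p-value per gene. Its log2 and p-value columns, named per the file headers, were read only for comparison with the values computed here. No column of per-sample values was left unused, and 0 rows lacked a gene identifier.

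Gene identifiers were used as the table gives them. A current symbol was found for 17253 genes, 163 more were named from the authors' deposited table, and 143 kept their identifier. Coordinates are from the Ensembl 115 annotation of BDGP6.54 and were matched by identifier. The genes of 32 lists were written before the data were examined, and 16 of the members written matched no gene.

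Total counts ranged from 19720070 to 36022790 per library. A count of 0 in a library allows up to 3 counts, which is 0.083 to 0.152 CPM (counts scaled to a library total of 1000000) at these depths. That floor covers counting error only, since reads without molecular identifiers are not independent molecules.

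Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and 8794 genes entered a quasi-likelihood F-test of LamDm0 against control, two-sided, with no block. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. "Adjusted p" of a gene means this value throughout. The standard error of a log2 fold change was its size divided by the square root of F. CPM are TMM-scaled and given as mean ± SD.

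Gene lists were tested with camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 between genes, and adjusted over the 32 lists. The test was repeated with the correlation estimated from the data, and with fry. For each list the members past the gene test were counted over all genes tested and, as a separate count, adjusted over the list alone.

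Genes named in the text follow a rule fixed before the data were examined. They are Lam and LamC; the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups; for each list up to 4 members past the threshold with the smallest p, or the 1 member with the smallest p where none passed; and the markers esg, Dl (named Delta in the current name table), Su(H), nub, Myo31DF, Hey, pros, Tk, upd3, Mhc and w. Genes named outside this rule are marked as such.

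The steps were tested on simulated counts for the LamDm0 against control comparison, drawn from the means, dispersions and library sizes of these libraries with 200 genes changed. Of the changed genes among the 8684 tested, 6% were recovered at a fold of 1.5, 68.2% at a fold of 2 and 92.2% at a fold of 4, and 5.3% of the calls were unchanged genes. In the simulated list test, run on 8696 genes, a list of 47 genes raised by a fold of 2 was called, and 0 of the 29 lists that share no member with it were called. Simulated genes were drawn independently of each other, whereas the correlation estimated from the data reached 0.89 for cytosolic ribosomal protein genes. The simulation therefore does not show how often lists of correlated genes are called falsely. It also drew the libraries of a group independently, without the closeness of some replicates that is described below. The share of 5.3% therefore need not hold for the real libraries.

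Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter, a minimum mean of 10 CPM, the 20 most abundant genes left out, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom without and with sample weights, a minimum absolute log2 fold change of 1, a threshold of 0.01, and for lists the estimated correlation, fry and the lamina list without Lam. Alternatives chosen after seeing the data left out a pair of LamDm0 libraries, summed the libraries in pairs, or left out mitochondrial genes. All 35 ways to split the 8 libraries into 4 and 4 were also tested.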

Results

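Gene expression was measured by RNA sequencing in whole guts of adult female flies, to ask how expression of the B-type lamin LamDm0 in enterocytes changes the gut transcriptome. There were 4 control libraries with 20954291, 19720070, 23347139 and 23176905 counts (replicates 1 to 4) and 4 LamDm0 libraries with 26687200, 22737593, 24006226 and 36022790. Between 10762 and 11358 genes had at least 1 count in a library. Mitochondrially encoded genes took 5.55% to 15.2% of the counts in control libraries and 8.53% to 21.85% in LamDm0 libraries. In principal component analysis the first component held 40.1% of the variance and separated all 4 LamDm0 libraries from all 4 controls. On the second, with 20.5%, control replicates 1 to 4 lay at -23.9, -19, 46.6 and 7. LamDm0 replicates 1 to 4 lay there at 15, -3.7, -20.2 and -1.9. The third, with 15.2%, separated LamDm0 replicates 1 and 2 from LamDm0 replicates 3 and 4.

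The expressed gene itself, Lam (FBgn0002525, chromosome arm 2L, 5542480 to 5546642 in BDGP6.54), had 18.3 ± 1.62 CPM in control guts and 3608 ± 957 CPM in LamDm0 guts (SD, n = 4 each). The control libraries held 18.5, 20.2, 16.2 and 18.3 CPM and the LamDm0 libraries 4190, 4647, 2894 and 2702 CPM, so each library matched its label. The log2 fold change was 7.62 ± 0.28 (SE; adjusted p = 6.4e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Counts per gene do not separate the transgene from the endogenous locus. LamC (FBgn0010397, 2R, 14570810 to 14575771), the A-type lamin, had 71.5 ± 15.4 CPM in control and 99.3 ± 13.2 CPM in LamDm0 guts, and did not pass (log2 fold change 0.47 ± 0.17, adjusted p = 0.13).

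The inner nuclear membrane genes Ote, bocks and LBR rose beside Lam. Of the 20 members of the nuclear lamina and envelope list that were tested, 5 were higher in LamDm0 guts, Lam among them, 0 were lower and 15 did not pass. Adjusted over the list alone, 6 were higher. Of genes for LEM-domain proteins, Ote, which encodes otefin, rose 6.43-fold from 0.862 ± 0.372 to 5.59 ± 1.32 CPM (adjusted p = 0.0021), and bocks rose 1.80-fold from 17.4 ± 1.28 to 31.3 ± 3.13 CPM (adjusted p = 0.0031). LBR, the lamin B receptor, rose 1.78-fold from 4.04 ± 0.437 to 7.18 ± 0.97 CPM (adjusted p = 0.011; 0.058 without LamDm0 replicates 3 and 4). The remaining call was baf, encoding the DNA-binding barrier-to-autointegration factor, at 1.56-fold (adjusted p = 0.017), named after its values were seen. The list median was 0.22 on the log2 scale and the list passed camera (adjusted p = 0.00012), but not with an estimated correlation (adjusted p = 0.43).

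**Figure D1:**
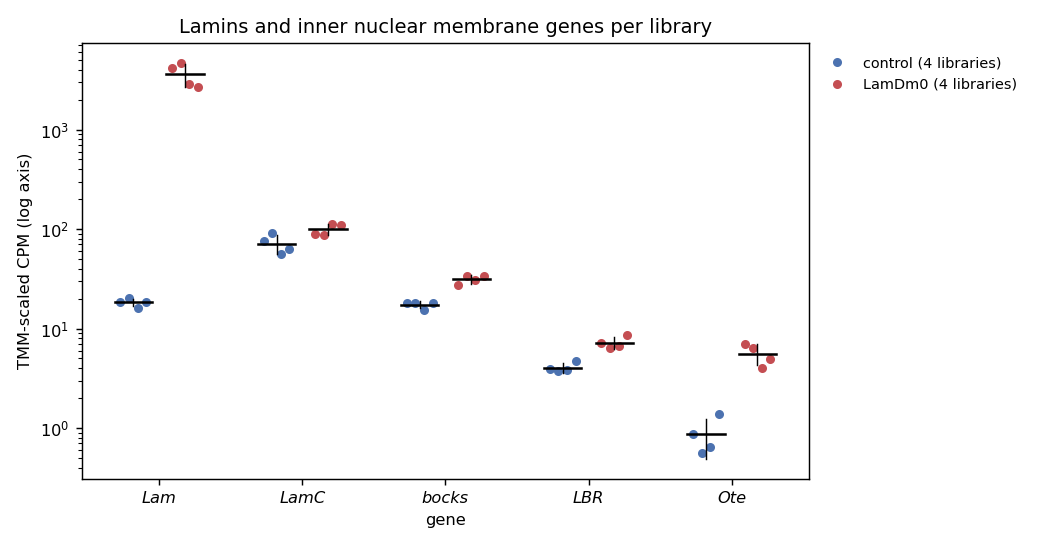
Lamin and inner nuclear membrane genes in each library, as TMM-scaled CPM on a log axis; points are the 4 libraries of a group, horizontal bars the mean and vertical bars the SD. Lam lies at 16.2 to 20.2 CPM in control and 2702 to 4647 CPM in LamDm0 libraries, and bocks, LBR and Ote do not overlap between the groups.

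Some digestive protease genes were lower in LamDm0 guts. Of 30 tested, 6 were lower, 0 were higher and 24 did not pass. Adjusted over the list alone, 7 were lower. The serine protease genes deltaTry and Jon66Cii fell 6.59-fold (99.1 ± 22.5 to 15 ± 8.16 CPM, adjusted p = 0.0052) and 5.67-fold (70.8 ± 2.84 to 12.6 ± 5.74 CPM, adjusted p = 0.0021). Jon66Ci fell 3.98-fold (adjusted p = 0.0032), and the abundant yip7 fell 2.46-fold from 17270 ± 2466 to 7022 ± 2779 CPM (adjusted p = 0.031). The list median was -0.58, and 3 of the 30 members had a positive log2 fold change. Without any 1 library other than LamDm0 replicate 2, 3 proteases were called. Camera passed (adjusted p = 1.9e-06) and lost the call with an estimated correlation (adjusted p = 0.53). Several of these genes, deltaTry and the Jon66C pair among them, have close copies that may share reads, so the split between copies is uncertain.

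Of the enterocyte identity and brush border list, 3 of 16 members were lower and 13 did not pass, with the same counts adjusted over the list alone. The 3 encode enzymes: the amylases Amy-d, which fell 2.87-fold (553 ± 187 to 192 ± 57.4 CPM, adjusted p = 0.016), and Amy-p, which fell 2.31-fold (1290 ± 378 to 559 ± 199 CPM, adjusted p = 0.039), and the alkaline phosphatase Alp4, which fell 2.72-fold (76.7 ± 29.0 to 28.2 ± 10.4 CPM, adjusted p = 0.037). The 2 amylase genes are near-identical copies, so their separate values are uncertain. Markers of enterocyte identity did not pass: Myo31DF, a brush border myosin, had 319 ± 7.49 CPM in control and 317 ± 40.6 CPM in LamDm0 guts (log2 fold change -0.01 ± 0.12, adjusted p = 0.98), and the transcription factor gene nub had 176 ± 29.1 and 149 ± 46.7 CPM (-0.24 ± 0.24, adjusted p = 0.59). The list median was -0.22. Camera gave an adjusted p of 0.041, and 0.49 with an estimated correlation, and did not pass without control replicate 1 or 2, without LamDm0 replicate 1, 2 or both (adjusted p up to 0.42), or with a minimum mean of 10 CPM (adjusted p = 0.069). The septate junction and polarity list had 0 calls among 24 members by edgeR, also when adjusted over the list alone, with a median of -0.01 and a camera adjusted p of 0.58 (0.007, downward, without LamDm0 replicates 3 and 4). In it 1 gene had an unadjusted p under 0.05 and DESeq2 called 1. Its smallest p belonged to the polarity gene baz (log2 fold change -0.60 ± 0.17, adjusted p = 0.06). Leaving out a library ended calls in this group: yip7 lost its call without any 1 of 7 libraries (adjusted p up to 0.087), Alp4 and Amy-p each without any 1 of 5 (up to 0.097 and 0.099), and Amy-d without LamDm0 replicate 4 (adjusted p = 0.052).

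**Figure D2:**
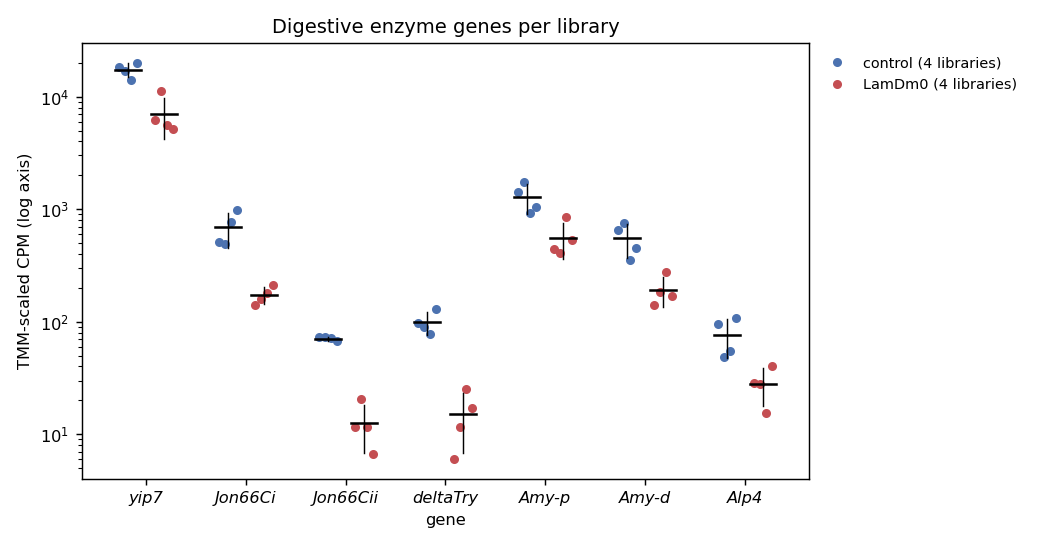
Genes of digestive proteases, amylases and the alkaline phosphatase Alp4 in each library, as TMM-scaled CPM on a log axis. Points are the 4 libraries of a group, horizontal bars the mean and vertical bars the SD. For each of the 7 genes every LamDm0 library lies below every control library, from yip7 (17270 CPM in control) to Jon66Cii (70.8 CPM in control).

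Some genes of DNA replication and the cell cycle were higher in LamDm0 guts. Of 47 members tested, 12 were higher, 0 were lower and 35 did not pass. Adjusted over the list alone, 23 were higher. RnrL, the large subunit of ribonucleotide reductase, rose 5.84-fold from 3.7 ± 2.23 to 21.6 ± 2.75 CPM (adjusted p = 0.0038), and Orc2, of the origin recognition complex, rose 4.47-fold from 0.463 ± 0.194 to 2.08 ± 0.463 CPM (adjusted p = 0.0066; 0.055 without LamDm0 replicates 3 and 4). The more abundant Top2, a DNA topoisomerase, and His2Av, a histone variant, rose 1.68-fold (21.1 ± 1.48 to 35.4 ± 2.81 CPM, adjusted p = 0.0034) and 1.64-fold (38.9 ± 1.45 to 63.6 ± 5.63 CPM, adjusted p = 0.0035). Named after their values were seen, PCNA rose 3.29-fold (adjusted p = 0.046) and the helicase subunit Mcm5 4.09-fold (adjusted p = 0.021). The list median was 0.97, 44 of 47 members had a positive log2 fold change, and camera passed (adjusted p = 3.7e-12) but not with an estimated correlation (adjusted p = 0.49). The number of members called ranged from 5 to 24 when 1 library was left out. It was 5 without LamDm0 replicate 3 or 4 or control replicate 1, 2 or 3, and 24 without control replicate 4, in which RnrL stood at 7.03 CPM against 2.42 to 2.8 CPM in the other controls. Among members with a mean of at least 10 CPM, 4 were called and the list median was 0.20.

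**Figure D3:**
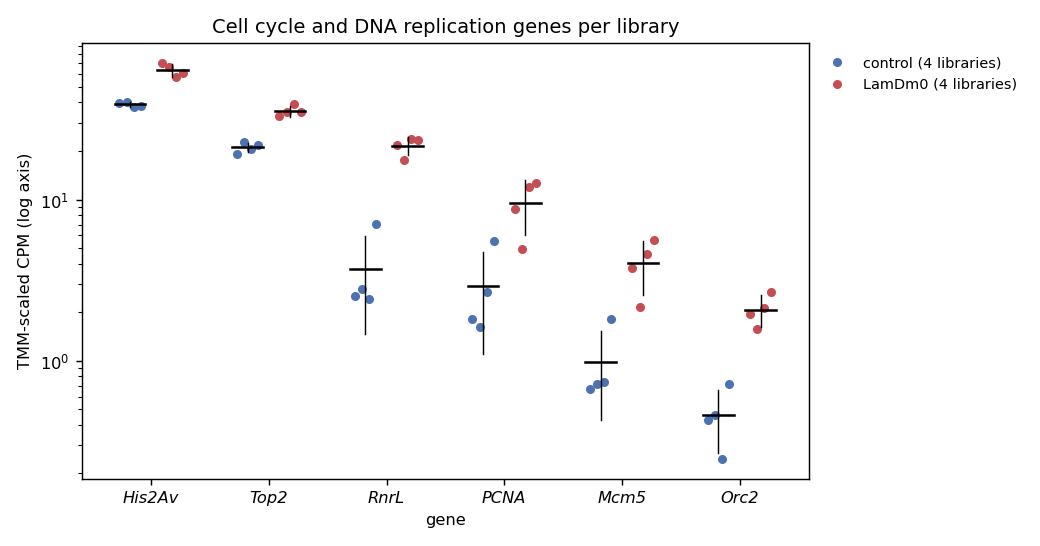
Cell cycle and DNA replication genes in each library, as TMM-scaled CPM on a log axis; points are the 4 libraries of a group, horizontal bars the mean and vertical bars the SD. RnrL lies between 2.42 and 7.03 CPM in control and between 17.7 and 23.6 CPM in LamDm0 libraries.

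Markers of stem cells, enteroblasts and enteroendocrine cells did not pass. By edgeR, 0 of 21 stem cell and enteroblast genes, 0 of 7 Notch targets and 0 of 24 enteroendocrine genes were called, over all genes or adjusted over the list alone, with medians of 0.04, 0.14 and 0.08 and camera adjusted p of 0.87, 0.74 and 0.74. At an unadjusted p under 0.05 there were 4, 0 and 2 such genes, and DESeq2 called 2, 0 and 1. The stem cell gene esg had 22.4 ± 8.36 CPM in control and 19.1 ± 6.69 CPM in LamDm0 guts (log2 fold change -0.23 ± 0.30, adjusted p = 0.7), and the Notch ligand Dl had 9.998 ± 3.37 and 11.4 ± 3.83 CPM (0.19 ± 0.31, adjusted p = 0.75). Su(H), the transcription factor of Notch signalling, had a log2 fold change of 0.25 ± 0.24 (adjusted p = 0.57), and Hey had 0 counts in all 8 libraries, which allows at most 0.083 to 0.152 CPM if its reads could be counted, which is not known. In enteroendocrine cells, the transcription factor gene pros had 3.2 ± 0.877 and 3.77 ± 1.37 CPM (adjusted p = 0.68) and the peptide gene Tk 36.4 ± 10.4 and 38.2 ± 12.3 CPM (adjusted p = 0.9). The smallest p in these lists belonged to stg, a cell cycle phosphatase (1.65 ± 0.50, adjusted p = 0.085; 0.02 without control replicate 4), E(spl)m6-BFM (1.34 ± 0.64, adjusted p = 0.24) and the peptide gene Mip (1.06 ± 0.33, adjusted p = 0.092). The enteroendocrine list passed camera upward with LamDm0 replicates 1 and 2 left out (adjusted p = 0.016, 4 members higher) and downward with LamDm0 replicates 3 and 4 left out (adjusted p = 0.038, 1 member lower). In the other alternatives it did not pass.

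The regenerative and stress signalling list gave 1 call in each direction among 33 members, with the same counts adjusted over the list alone. The EGFR ligand gene Krn rose 1.46-fold (12.5 ± 1.38 to 18.2 ± 2.36 CPM, adjusted p = 0.034), a call that ended without any 1 of 7 libraries (adjusted p up to 0.091). TotM, a stress-induced secreted protein gene, fell 15.1-fold from 1.5 ± 1.07 to 0.0992 ± 0.0709 CPM (adjusted p = 0.012; 0.099 without LamDm0 replicates 3 and 4). The cytokine gene upd3 had 2.29 ± 1.31 and 5.27 ± 2.06 CPM (1.21 ± 0.46, adjusted p = 0.15). The list median was -0.05 (camera adjusted p = 0.74).

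Over all 8794 genes, 419 were higher and 287 lower in LamDm0 guts, and 201 and 130 of them changed by at least 1 on the log2 scale. The groups did not overlap for 694 of the 706 genes called; over all genes tested this share was 17.3%, where chance gives 2.9%. Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest increases, after lncRNA:CR40469 (282-fold, 0.466 ± 0.226 to 133 ± 60.9 CPM, adjusted p = 9.5e-05) and Lam, were asRNA:CR45600 (50.0-fold), the lysozyme gene LysS (42.2-fold), CG9360 (37.5-fold), CG43055 (15.6-fold), lncRNA:CR44138 (15.6-fold) and LysC (14.2-fold). Within the same limits, the largest decreases were FBgn0085364, which has no symbol in the tables used here (126-fold, 126 ± 33.4 to 1.02 ± 0.492 CPM, adjusted p = 3.5e-05), CG10725 (41.5-fold), the cell adhesion gene Dscam4 (33.3-fold), the small heat shock gene Hsp23 (26.8-fold), the cytochrome P450 gene Cyp6a2 (22.9-fold), Ugt49B1 (16.3-fold), CG12934 (12.9-fold) and CG11700 (10.5-fold). Within a group some of these were uneven. Hsp23 had 129 CPM in control replicate 2 and 5.6 to 25.4 CPM in the others, and its log2 fold change went from -4.75 to -3.03 without that library. CG10725 and CG12934 had 35.0 and 31.9 CPM in control replicate 1, 37.0 and 36.4 in 2, 6.85 and 10.7 in 3, and 4.02 and 7.65 in 4. CG43055 and Ugt49B1 had 71.4 and 9.98 CPM in LamDm0 replicate 1, 61.2 and 14.9 in 2, 333 and 1.45 in 3, and 328 and 1.07 in 4. The calls of CG10725 and CG12934 ended without either pair of LamDm0 libraries (adjusted p = 0.051 to 0.075), that of CG43055 without LamDm0 replicates 3 and 4 (adjusted p = 0.069), that of CG10725 by limma-voom (adjusted p = 0.098), and those of all 4 with libraries summed in pairs (adjusted p = 0.078 to 0.17). The log2 fold change of Ugt49B1 went from -4.03 to -4.75 without LamDm0 replicate 2 and that of CG43055 from 3.97 to 4.65 without control replicate 4. The call of Hsp23 ended without any 1 of 5 libraries (adjusted p up to 0.082), and that of CG43055 without control replicate 1 or 2 (adjusted p up to 0.054). asRNA:CR45600 is antisense to another gene, so its counts are uncertain. Without control replicate 1, control replicate 2, LamDm0 replicate 3 or LamDm0 replicate 4 the number of genes called was 346, 396, 397 and 387. With the counts of replicates 1 and 2 and of 3 and 4 summed in each group, 72 genes were called, 36 in each direction.

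Genes of detoxification moved in both directions. Of 63 cytochrome P450 genes, 12 were higher and 5 lower (12 and 11 adjusted over the list alone): Cyp6a23 rose 4.41-fold from 280 ± 73.2 to 1236 ± 58.3 CPM, its neighbour Cyp6a17 3.65-fold and Cyp6a14 2.34-fold, while Cyp6a2 fell 22.9-fold from 27.8 ± 2.8 to 1.19 ± 0.322 CPM (adjusted p of at most 0.00097 for the 4). The other lower P450 genes, named after their values were seen, were Cyp4e3, Cyp6v1, Cyp4ac3 and Cyp6a18. Among 44 glutathione S-transferase and oxidative stress genes, 5 were higher and 5 lower (7 and 6 adjusted over the list alone). GstD5 and GstD9 rose 5.51-fold and 2.63-fold, and GstE1 and GstE7 fell 3.54-fold and 3.11-fold (adjusted p of at most 0.0072). GstE11, GstO1 and GstS1 were also higher and GstE3, Gclc and Prx6c also lower, named after their values were seen. The medians were -0.07 and -0.09 and neither list passed camera (adjusted p = 0.96 and 0.73). For P450 genes camera pointed up and the mean was 0.16, against a negative median.

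Most lysozyme genes were higher and some chaperones of the endoplasmic reticulum lower. Of 6 lysozyme genes 4 were higher (5 adjusted over the list alone): LysS (5.87 ± 5.51 to 248 ± 150 CPM), LysC, LysE (6.42-fold) and LysD (5.99-fold, adjusted p = 0.049). LysC, which the annotation calls a pseudogene, LysD and LysE are near-identical copies, so their separate values are uncertain. The list passed camera (adjusted p = 6.9e-05; 0.49 with an estimated correlation). The call of LysD ended without any 1 of 7 libraries and that of LysE without any 1 of 5 (adjusted p up to 0.12 and 0.088). Without control replicate 2 the log2 fold changes of LysS, LysD and LysE went from 5.40, 2.58 and 2.68 to 6.30, 3.60 and 3.36. In the ER stress and secretory list 4 of 24 genes were lower and 0 higher (5 lower adjusted over the list alone): the ER chaperones Hsc70-3 (1719 ± 137 to 856 ± 122 CPM) and Gp93 (1054 ± 204 to 497 ± 52.7 CPM), the disulfide isomerase family gene CaBP1 (2.04-fold; adjusted p = 0.07 without LamDm0 replicates 3 and 4) and Der-2 (1.42-fold, lost without any 1 of the 8 libraries, adjusted p up to 0.088). That list passed camera (adjusted p = 0.00025; 0.53 with an estimated correlation). Among 17 heat shock and chaperone genes, Hsp60A rose 1.88-fold and Hsp70Bb, which has near-identical copies, 2.57-fold, and Hsp23 fell (2 higher and 4 lower adjusted over the list alone). Camera pointed up for that list (adjusted p = 0.76), against a median of -0.08 and a mean of -0.84. Of 30 antimicrobial and immune genes, the call was Drsl2 (0.31 ± 0.286 to 6.18 ± 4.59 CPM, adjusted p = 0.04), which was higher in 3 of 4 LamDm0 libraries and lost its call without any 1 of 7 libraries (log2 fold change 4.32, and 5.10 without control replicate 2). Adjusted over the list alone 0 were called, and camera pointed down (adjusted p = 0.025; 0.76 with an estimated correlation). It did not pass without control replicate 1 or 2, LamDm0 replicate 2 or 4, or LamDm0 replicates 1 and 2 (adjusted p up to 0.21).

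Metabolic and housekeeping lists held few calls. In carbohydrate digestion and sugar transport the 2 amylases were lower among 26 genes (2 adjusted over the list alone; camera adjusted p = 0.76). In lipid digestion and metabolism, whd, the carnitine palmitoyltransferase of fatty acid oxidation, fell 2.19-fold (291 ± 39.5 to 133 ± 20.3 CPM, adjusted p = 0.0041) and Mtp rose 1.39-fold among 31 genes, with the same counts adjusted over the list alone (camera adjusted p = 0.73, median -0.12, mean 0.02). Of 82 cytosolic ribosomal protein genes, RpS24 was lower (1.94-fold, adjusted p = 0.037) and 0 were called adjusted over the list alone. Of the 82, 2 had a positive log2 fold change, the median was -0.25, and camera passed (adjusted p = 8.7e-06; 0.97 with an estimated correlation). The mean log2 difference of the list from the control mean was 0.06, 0.13, -0.80 and -0.72 in LamDm0 replicates 1 to 4 and 0.14, 0.09, 0.04 and -0.26 in the controls. Without LamDm0 replicates 3 and 4 the list pointed upward and did not pass (adjusted p = 0.12). Among 72 mitochondrial ribosomal protein genes mRpS6 rose 1.64-fold and mRpL37 fell 1.31-fold (1 higher and 0 lower adjusted over the list alone). Camera gave that list an adjusted p of 0.088, and it passed upward without LamDm0 replicate 3, 4 or both, without control replicate 3, with no low-count filter and with a minimum mean of 10 CPM (adjusted p between 7.9e-07 and 0.045). By edgeR 0 of 63 oxidative phosphorylation genes were called, also adjusted over the list alone. The 1 gene with an unadjusted p under 0.05 was ND-18 (-0.22 ± 0.09, adjusted p = 0.17). DESeq2 called 1, and the camera adjusted p was 0.72. That list passed camera downward without LamDm0 replicate 2 (adjusted p = 0.015) and without LamDm0 replicates 1 and 2 (adjusted p = 0.0015). VhaAC39-2 was lower among 21 vacuolar ATPase and acid region genes (4.18-fold, adjusted p = 0.02; camera adjusted p = 0.02, 0.76 with an estimated correlation). The zinc transporter family gene Zip42C.2 was lower among 22 metal handling genes (2.63-fold, adjusted p = 0.0079; camera adjusted p = 0.041, 0.49 with an estimated correlation). HDAC1 was higher among 36 chromatin silencing genes (1.47-fold, adjusted p = 0.018; camera adjusted p = 0.53), and the homeobox gene hth was lower among 23 midgut region transcription factors (1.45-fold, adjusted p = 0.014, and 0.065 without LamDm0 replicates 3 and 4; camera adjusted p = 0.12). Camera did not pass for the acid region list without LamDm0 replicate 1, 2 or both, without control replicate 3 or with libraries summed in pairs (adjusted p up to 0.44). For metal handling it did not pass without LamDm0 replicate 1 or 4, either pair of LamDm0 libraries or control replicate 2, or with no low-count filter (adjusted p up to 0.094). The midgut region list passed downward with a minimum mean of 10 CPM (adjusted p = 0.045) and without LamDm0 replicates 3 and 4 (adjusted p = 0.041). Adjusted over the list alone the last 4 lists had 1, 2, 1 and 1 calls in the same directions. The calls of Mtp, RpS24, mRpL37, VhaAC39-2 and HDAC1 ended without any 1 of 6, 6, 7, 3 and 3 libraries (adjusted p up to 0.092, 0.1, 0.13, 0.061 and 0.063).

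Markers of the other tissues a dissected gut could carry gave few calls. By edgeR 0 of 26 muscle genes, 0 of 12 tracheal genes, 0 of 9 hemocyte genes, 0 of 12 fat body and hemolymph genes and 0 of 12 foregut, crop and hindgut genes passed. Adjusted over each list alone the count was 0 apart from ush, lower among the hemocyte genes (-0.70 ± 0.19, adjusted p = 0.055 over all genes). At an unadjusted p under 0.05 these 5 lists held 1, 1, 2, 1 and 3 genes, and DESeq2 called 1, 1, 2, 0 and 0. Mhc, muscle myosin, had 382 ± 89.6 CPM in control and 321 ± 154 CPM in LamDm0 guts (adjusted p = 0.68). The smallest p of the other lists belonged to Mlc-c (0.34 ± 0.11, adjusted p = 0.1), sima (-0.41 ± 0.13, adjusted p = 0.086) and bowl (-0.59 ± 0.21, adjusted p = 0.12). Of these sima and bowl passed without control replicate 4 (adjusted p = 0.038 and 0.04), and ush without LamDm0 replicate 3 (adjusted p = 0.046). The fat body median was 0.76 and apolpp, a lipoprotein gene, had 33.4 ± 22.6 and 156 ± 50.4 CPM (2.22 ± 0.72, adjusted p = 0.1; 0.013 without control replicate 3, which stood at 2.12 CPM). Of 12 neuronal genes futsch and Cadps were higher (4.11-fold and 2.17-fold, adjusted p = 0.008 and 0.024; list median -0.12, mean 0.04). Of 5 ovary, eggshell and germline genes Cp18 was higher (0.136 ± 0.0646 to 0.606 ± 0.21 CPM, adjusted p = 0.029), and of 20 Malpighian tubule genes the transporter Oatp58Db was lower (12.2-fold, adjusted p = 0.0057; 0.063 without LamDm0 replicates 3 and 4). These 3 lists had the same counts adjusted over the list alone. The calls of Cadps and Cp18 ended without any 1 of 4 and 7 libraries (adjusted p up to 0.069 and 0.078). The tubule list passed camera (adjusted p = 0.037; 0.53 with an estimated correlation), but not without control replicate 1 or 4, LamDm0 replicate 1, 2 or 4, or LamDm0 replicates 1 and 2 (adjusted p up to 0.21), or with a minimum mean of 10 CPM (adjusted p = 0.093). The camera adjusted p of the other 7 lists lay between 0.31 and 0.97. Of these, muscle passed downward without LamDm0 replicate 1 (adjusted p = 0.0496), hemocytes upward without LamDm0 replicates 3 and 4 (adjusted p = 0.047) and fat body upward with libraries summed in pairs (adjusted p = 0.02). The eye colour gene w, a common marker in fly transgenes, had 166 ± 143 and 93.0 ± 10.4 CPM (adjusted p = 0.33), with 380 CPM in control replicate 2.

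**Figure D4:**
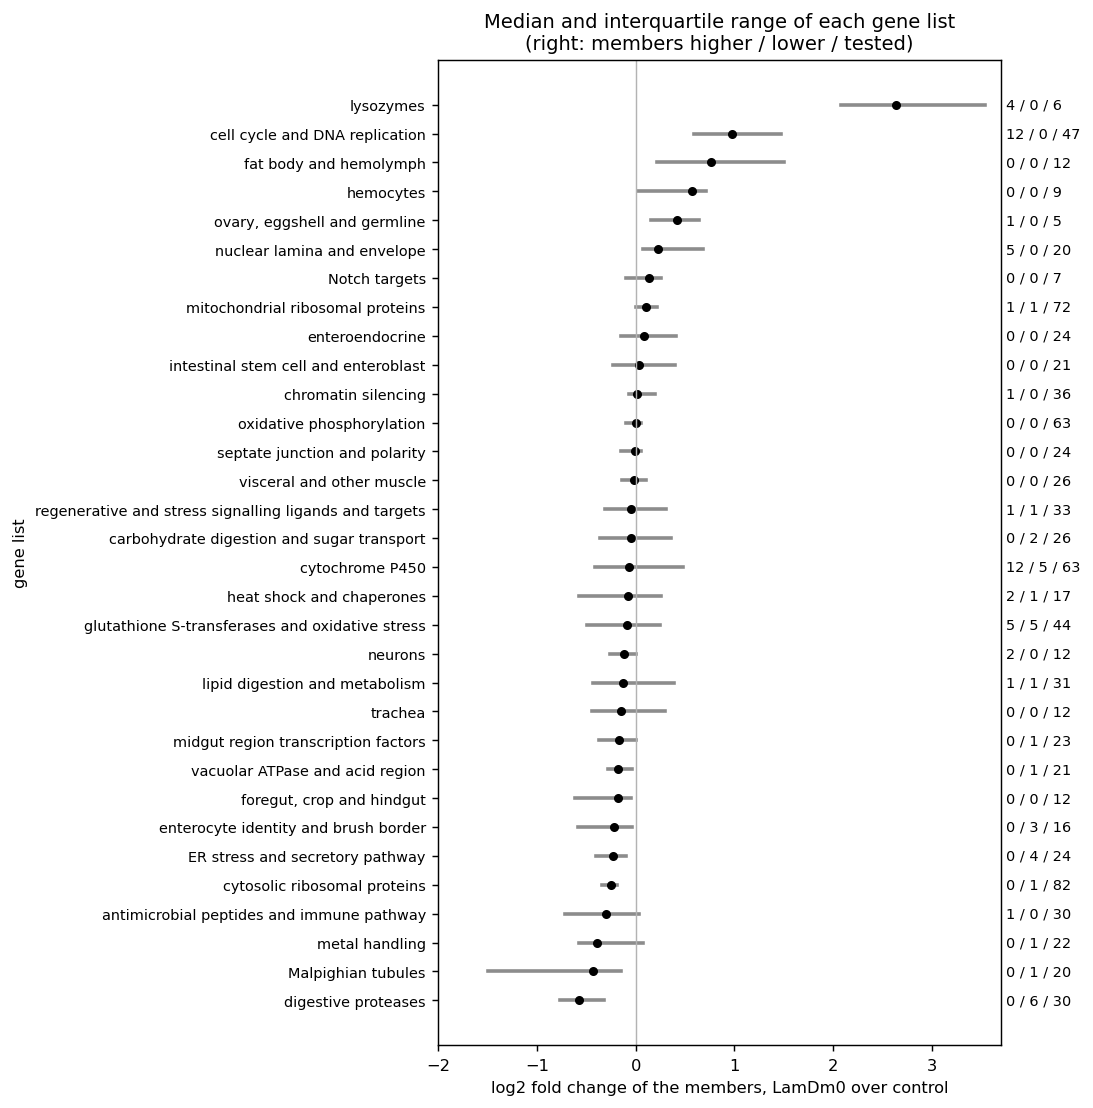
Log2 fold changes of the members of each of the 32 gene lists, LamDm0 over control; points are the medians, grey bars run from the first to the third quartile, and the numbers at the right are members higher, lower and tested. The cell cycle list (median 0.97) and the digestive proteases (median -0.58) lie on opposite sides of 0.

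In the authors' deposited table, 671 genes were higher and 612 lower at an adjusted p under 0.05, and 705 of the 706 genes called here were also called there in the same direction. The deposited table gives Lam a log2 fold change of 7.16.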

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

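In groups of 4, a library was set apart where its distance to the nearest other library, divided by the whole range of its group, exceeded Dixon's critical value at 95%. This was tested for the named genes, library measures and summed markers of other tissues, 188 groups in all, of which chance would set apart about 9.4; 13 were found.

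In control replicate 2, w stood at 379.6 CPM against 82 to 114 CPM in the other controls, Hsp23 at 129.4 CPM against 5.6 to 25.4 CPM, LysD at 384.3 CPM against 59.9 to 93.9 CPM and LysS at 14.1 CPM against 2.73 to 3.83 CPM. The replication gene RnrL stood at 7.03 CPM in control replicate 4 against 2.42 to 2.8 CPM in the others, and bocks at 15.48 CPM in control replicate 3 against 18.0 to 18.1 CPM. LamDm0 replicate 2 was apart for the protease gene yip7 (11140 CPM against 5191 to 6189 CPM), for whd (102.6 CPM against 141 to 146 CPM), for Cyp6a2 (0.7142 CPM against 1.31 to 1.42 CPM), for ND-18 (84.7 CPM against 74.1 to 75.3 CPM) and for the summed foregut, crop and hindgut genes (442.1 CPM against 822 to 845 CPM). The summed Malpighian tubule genes stood at 1866 CPM in control replicate 1 against 1620 to 1641 CPM in the other controls. Mitochondrially encoded genes took 21.85% of the counts of LamDm0 replicate 1 against 8.53% to 10.63% in the other LamDm0 libraries.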

How the results depend on the processing

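The alternatives that left out a pair of LamDm0 libraries, summed libraries in pairs or left out mitochondrial genes were chosen after seeing the data; the others were fixed before. The count of genes called (706 in all, 419 higher and 287 lower) stayed within 1.5 times under RLE and upper-quartile scaling, no filter, limma-voom, and without the 20 most abundant or the mitochondrial genes; across these scalings the share that was higher ran from 56.2% to 64.7%, against 59.3%, and the median of all genes from -0.01 to 0.03. None of the 706 genes changed sign under any fit run. A minimum mean of 10 CPM tested fewer genes and left 465 calls (275 higher, 190 lower) with 4 cell cycle members. A minimum log2 fold change of 1 left 331 (201 and 130), and a threshold of 0.01 left 226 (149 and 77). DESeq2 called 1287 (659 and 628), with 6 lamina genes higher and 1 lower, and 11 proteases lower. It also called 2 stem cell genes, 1 enteroendocrine gene and 19 cell cycle genes higher. Limma-voom with sample weights called 2604 (1358 and 1246): 8 lamina genes higher, 5 enterocyte genes lower, 16 proteases lower, 4 stem cell genes higher and 1 lower, and 7 enteroendocrine and 36 cell cycle genes higher. The cause of the larger counts was not tested.

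With the replicate number as a block, 332 genes were called (211 higher, 121 lower), with 1 enterocyte and 3 protease genes lower; 16 named genes lost the call, Ugt49B1 and CG12934 among them (adjusted p = 0.066 and 0.071), and the enterocyte list did not pass camera (adjusted p = 0.054). Deviations of same-numbered libraries from their group means correlated at -0.18, -0.06, -0.37 and -0.03, and 0 of the 4 control libraries correlated best with the LamDm0 library of its number, so the numbers were not read as pairs.

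Leaving out 1 library gave 346 to 654 calls in all, 214 to 387 higher and 132 to 267 lower. Cell cycle members called ran from 5 to 24, proteases lower from 3 to 7, enterocyte genes lower from 1 to 3, stem cell genes higher from 0 to 2, and lists passing camera from 8 to 12. Of the 61 named genes that were called, 43 kept the call without any 1 library and 18 lost it at least once, with fewer samples in each fit; 12 lost it without LamDm0 replicates 1 and 2, 23 without 3 and 4 and 44 with libraries summed in pairs. Without LamDm0 replicates 1 and 2, 878 genes were called (452 higher, 426 lower); 13 proteases were lower, 1 enterocyte gene was higher and 0 lower, and 4 enteroendocrine genes were higher, and that list passed camera upward (adjusted p = 0.016). Without LamDm0 replicates 3 and 4, 439 genes were called (302 higher, 137 lower), among them 3 lamina, 3 protease and 3 cell cycle members. The list medians there were 0.74 for cell cycle genes and -0.34 for proteases. In the same setting 1 enteroendocrine gene was lower and that list passed camera downward (adjusted p = 0.03766). The ribosomal protein list turned upward there (camera adjusted p = 0.1186). With libraries summed in pairs, 2 sums against 2, 72 genes were called (36 and 36), with 2 lamina, 0 enterocyte, 1 protease and 1 cell cycle members.

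Of the 32 lists 11 passed camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.43; 2 lists had an unadjusted p under 0.05) and 4 by fry (lamina, lysozymes, cell cycle and metal handling); all 11 passed without Lam in the lamina list. Fewer of the low genes were recovered: in simulated data, of genes changed by a fold of 2, 38.5% of 26 below a mean of 10 CPM were recovered and 87.5% of 40 at or above it. By list, calls by camera ended without any 1 of 5 libraries for Malpighian tubules, 4 for enterocyte and for immune genes and 3 for the acid region and for metal handling, with fewer samples in each fit.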

Other observations

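The tests of released silent genes, scaling, germline RNA, the share of stem cells and the share of enterocytes were chosen after the results were seen. The other tests were fixed before, but the fits without a pair of LamDm0 libraries, which 1 of them uses, were chosen after seeing the data.

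Some genes outside the fixed rule, named after their values were seen, differed widely between libraries of the same group. The yolk protein gene Yp1, which fat body and ovary express, stood at 2.86 CPM in control replicate 3, at 203 to 365 CPM in the other controls and at 364 to 774 CPM in LamDm0 libraries (log2 fold change 1.29 ± 0.95, adjusted p = 0.46), and Yp2 and Yp3 were at 4.73 and 7.74 CPM in that library. The small heat shock gene Hsp26 stood at 65.8 and 265 CPM in control replicates 1 and 2, at 4.04 and 4.11 CPM in control replicates 3 and 4 and at 3.33 to 5.61 CPM in LamDm0 libraries (adjusted p = 0.083), and Hsp27 at 29.9, 174, 2.51 and 2.15 CPM in the controls. The tubule gene Uro ranged from 0.0986 to 58.4 CPM in controls and from 0.0795 to 34.7 CPM in LamDm0 guts (adjusted p = 0.63).

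Some libraries lay close to each other. Over genes, the chi-square of the counts divided by its degrees of freedom was 26.8 between control replicates 1 and 2, 84.3 between control replicates 3 and 4 and 45.6 between LamDm0 replicates 3 and 4, and 180.7 to 382.4 for the other pairs within a group (208.4 for LamDm0 replicates 1 and 2), so no pair differed by less than sampling noise. The labels give no batch to set beside this.

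Of the 35 splits of the 8 libraries into 4 and 4, the real one was the 1 with as many as 706 called genes. A share of 1 in 35 is the smallest these splits can give. It can be read as a share under 0.05 only if the 8 libraries are exchangeable. The close libraries described above put that in doubt, so chance is not excluded. The highest other count was 151, in the split that joins LamDm0 replicates 1 and 2 with control replicates 3 and 4. Of splits that keep replicates 1 and 2, and 3 and 4, of each group together there are 3 (706, 151 and 0 genes), too few for a share under 0.05. By edgeR 33 of the 34 other splits called 0 genes. The number of lists passing camera does not set the real split apart: 19 of the 35 splits gave 11 or more, and the highest other gave 18. For the cell cycle list 2 splits gave a camera p as small as the real 1.17e-13 (smallest other 1.54e-24), and for the proteases 4 splits did (real 1.21e-07, smallest other 1.19e-15), so chance is not excluded for these 2 values. For the lamina list 1 split, the real one, did (1.89e-05, smallest other 0.000452). That list holds Lam, which was expressed in the LamDm0 group by design, and the splits were not repeated without it. The result therefore does not test its other members. In the other splits 0 cell cycle members and 0 proteases were called by edgeR, against 12 and 6. Because 33 of those 34 splits called 0 genes of any kind, this is no separate support for the 2 lists.

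The rise of the cell cycle genes was set against 3 explanations. A scaling factor shared by all genes of a library would move genes of like expression alike, and the list median lay 0.92 (bootstrap SE 0.11) above that of 10000 random lists matched on expression (0.05, central 95% from -0.11 to 0.20), which argues against it. RNA carried over from the ovary would bring germline and eggshell transcripts, whose summed level without BicD differed by 1.03 ± 0.72 CPM (SE), with osk at 0.0243 and 0.0346 CPM. With BicD the sum was 95.5 ± 3.07 CPM in control and 106.4 ± 13.95 CPM in LamDm0 guts (SD). The 4 called members of at least 10 CPM, RnrL, RnrS (named after its values were seen), Top2 and His2Av, rose by 17.9 ± 1.8, 22.9 ± 5.9, 14.4 ± 1.6 and 24.7 ± 2.9 CPM, more than the sum without BicD. How much of these markers and of these 4 genes ovary RNA holds was not measured, so carry-over is left open for them. For the lower members it stays open too, and there 2 SE above the germline sum and 2 SE below the rise of PCNA (6.65 ± 2 CPM) hardly part (2.46 and 2.66). They overlap without TMM scaling (3.14 and 2.54). This reading is stricter than the bound first written down and was settled with the values in view. A larger share of stem and progenitor cells would raise their markers alike. The third quartile of the 19 stem cell and enteroblast genes outside the cell cycle list was 0.25, below the cell cycle median of 0.97. With a minimum mean of 10 CPM, however, the cell cycle median was 0.20 and that of the whole stem cell list -0.17. Mean log2 levels of the 2 whole lists also varied together within groups. LamDm0 replicate 2 was the lowest LamDm0 library in both (-0.42 for stem cell and 0.29 for cell cycle genes). Control replicate 4 was the highest control in both (0.43 and 0.34). A larger share is therefore not excluded. More cycling among progenitors, or replication in enterocytes, may remain as hypotheses and were not tested.

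The fall of the digestive proteases was weighed in the same way. The list median of -0.58 lay -0.46 (bootstrap SE 0.08) from that of random lists matched on expression (-0.12). It was outside the central 95% of those lists (-0.24 to 0.00), and it was -0.60 under RLE and -0.55 under upper-quartile scaling. These values argue against a shared scaling factor for this list, although less 2 SE the gap just reaches the bound of -0.3 that was set for excluding it. A smaller share of enterocytes would lower their other genes too. The 16 genes of the enterocyte list had a median of -0.22, but their first quartile, -0.59, reached the protease median of -0.58. They include betaTry and Jon65Aiv, which are also on the protease list, so the quartile is not one of other genes alone. The fixed enterocyte markers Myo31DF and nub had log2 fold changes of -0.01 ± 0.12 and -0.24 ± 0.24 (SE). A smaller share is left open. Whether 2 of the 4 LamDm0 libraries carry the fall cannot be told: the median was -0.90 without replicates 1 and 2 and -0.34 without replicates 3 and 4. Both lie below the bound of -0.3 written for excluding this, the second by less than the bootstrap SE of 0.08. That SE came from the fit of all 8 libraries, and asking for it was stricter than the written bound. A lower output of these enzymes per enterocyte may be a candidate explanation, open as untested.

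Changes of at least 3 on the log2 scale with no overlap between groups numbered 56, 35 higher and 21 lower. If the 2 stocks differ in genetic background, such genes could lie in shared segments: 20.8% of the 53 with coordinates had another within 100 kb (17.6% without lysozymes), against a median of 11.3% and an upper end of 22.6% for the central 95% of 10000 random sets matched on expression, which decides neither way. Release of silent genes by LamDm0 would make most of them higher: 62.5% were (exact 95% interval 48.5% to 75.1%), which also leaves it open. Background and LamDm0 cannot be told apart for these genes, because each genotype came as 1 group.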
